A study of Mus musculus with 18 samples.

How the data were processed

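Expression had been measured on 18 mouse genome oligonucleotide arrays: 3 of normal liver, 7 of WT tumours, 5 of Tlr4-mutant tumours and 3 of tumours from antibiotic-treated WT mice. The deposited values are log2 GCRMA signals, background-corrected and summarised per probe set by the authors, per the submitters' processing notes, which do not give the GCRMA version. Group and sample numbers were taken from the labels, and 0 values were left unmapped to a sample. The arrays carry 45101 probe sets, of which 64 are controls, 34958 list 1 gene symbol, 932 several and 9160 none. Symbols were checked through Entrez identifiers against a gene table on mouse assembly 38, where 34754 probe sets were found and 0 symbols changed.

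Probe sets were kept when they exceeded log2 4 on at least 3 arrays, which left 16663, of them 14689 with 1 symbol. Each gene was represented by its kept probe set of highest mean, chosen without regard to group, so that 9053 genes were tested; 3586 of them had more than 1 kept probe set. Probe sets without a single symbol (1974) were tested apart. Arrays have no read depth. Their limit is signal over background, and a group with every array below log2 4 was treated as dim: the fold change was computed against log2 4 and given as at least that large.

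A linear model with 4 group means was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3, with moderated variances and Benjamini-Hochberg adjustment over the 9053 genes; an adjusted p under 0.05 counted as changed. The 3 tumour-to-tumour contrasts (mutant against WT, antibiotic against WT, mutant against antibiotic) and 3 tumour-to-normal contrasts were tested, all two-sided. Whether groups were apart was judged by every sample of the first lying above or below every sample of the second. Gene sets were 36 hand-written lists of liver, tumour, signalling and cell type genes, named where their results are given. They held 787 genes, of which 699 are on the array and 510 were tested, and the 30 lists with at least 5 tested genes were examined with camera at its preset correlation of 0.01, with camera and an estimated correlation, and with fry. Camera asks whether a list moves more than other genes, and fry whether its genes move one way on balance. The 3' minus 5' control differences were compared by two-sided exact permutation tests, adjusted over 8 tests.

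The comparisons, lists, thresholds and alternatives were fixed before the data were examined. So was the rule for naming genes. It named the 5 largest rises and falls among genes past 0.05 whose groups did not overlap, filled up to 5 with the non-passing genes of smallest p. It added 2 members of each list with a passing member (for WT tumours against normal liver, 2 in each direction of the lists that passed camera) and the 2 largest changes of lists without one. Tlr4, Ereg, Afp, Gpc3, Mki67, Cyp7a1, Col1a1, Cd14 and Lbp were always named. Genes named outside the rule are said to have been chosen after their values were seen.

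Alternatives were no filter, a filter at log2 6, the mean of a gene's probe sets, all probe sets one by one, removal of probe sets that may share sequence with other transcripts, centred arrays, quantile normalization, robust and trended variances, array weights, a fit of only the compared groups, a 2-fold minimum, an adjusted p under 0.01 and leaving out each array in turn. Leaving out WT tumours 17 and 19 together was added after seeing the data. The correlation of the mutant and antibiotic effects across genes was compared with 100 simulations of unchanged groups that share the WT tumours, each gene drawn independently, and with splits of the WT tumours. Gene counts and list counts were also taken over other splits of the same arrays, at most 100 drawn with seed 1.

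The procedure was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold among 9053, using the group sizes and spread of the arrays. It recovered 60% and 85% for WT tumours against normal liver, 73% and 95% for mutant against WT tumours, 63% and 87% for antibiotic against WT tumours, and 67% and 93% for mutant against antibiotic tumours. False calls numbered 9 of 154, 11 of 179, 9 of 159 and 11 of 171. Of 100 unchanged lists of 20 genes 5 had an unadjusted camera p under 0.05 in the mutant contrast, and a shifted list was found at an adjusted p under 0.05. The simulated genes were independent, so this does not test camera on genes that move together. Figures were drawn with python 3.11.15 and matplotlib 3.10.9.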

Results

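Gene expression was measured on 18 oligonucleotide arrays, 1 for each sample of liver or tumour from male mice, in a study of how Tlr4 and the intestinal microbiota promote hepatocellular carcinoma (HCC). Tlr4 encodes the receptor for bacterial lipopolysaccharide. Normal liver was represented by 3 samples of untreated mice of the wild-type (WT) strain C3H/HeOuJ, 15 weeks old. HCC lesions of WT mice were represented by 7 samples, taken at 54 weeks of age after 100 mg/kg of the liver carcinogen diethylnitrosamine in week 12 and 6 injections of 0.5 ml/kg of the hepatotoxin CCl4 between weeks 13 and 23. A further 5 samples were lesions of C3H/HeJ mice given the same regimen, whose Tlr4 carries the P712H change that blunts the response to lipopolysaccharide. The last 3 samples were lesions of WT mice that in addition drank ampicillin, neomycin and metronidazole (1 g/l each) and vancomycin (500 mg/l) from week 10. No source used here states that the samples of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical. The number of arrays, down to 3 in a group, limits the precision.

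The median log2 value of the expressed probe sets lay between 6.69 and 6.85 on the 18 arrays, and 14427 to 15275 probe sets per array exceeded log2 4. The first principal component held 41.0% of the variance and separated the 3 normal livers from all 15 tumours. The second held 14.4% and set WT tumours 17 and 19 apart from the other arrays. The 3' minus 5' difference of the Gapdh control probe sets was 1.52 ± 0.13 (log2, SD, n = 3) in normal liver and 0.42 ± 0.15 (SD, n = 7) in WT tumours, a difference of -1.10 (two-sided exact permutation test, p = 0.00833, adjusted p = 0.0333 over 8 tests). For beta-actin the values were 3.90 ± 0.31 and 2.15 ± 0.17, a difference of -1.76 (exact permutation p = 0.00833, adjusted p = 0.0333), so 3' bias was larger in normal liver. With 120 ways to split these 10 arrays, 0.00833 was the smallest p that the test could give. The spiked-in control transcripts were also bright on the normal arrays alone: dap read 10.3 ± 0.18 (log2, SD, n = 3) there and 1.93 ± 0.11 (SD, n = 15) in tumours. Labelling batch, RNA quality and tissue therefore cannot be told apart in any contrast of tumour with normal liver, and neither can the difference in age.

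**Figure D1:**
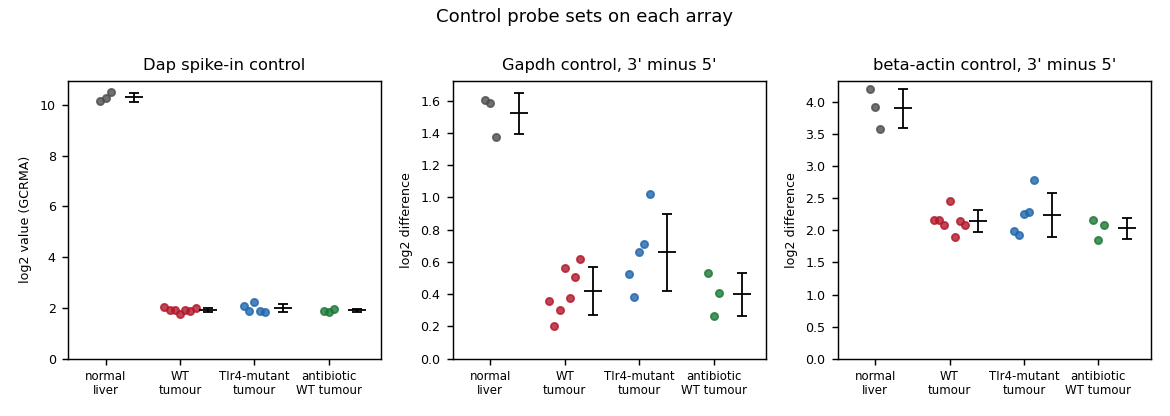
Log2 signal of the dap spike-in and the 3' minus 5' log2 difference of the Gapdh and beta-actin control probe sets, with a point per array in each of the 4 groups and a bar for the mean ± SD. The 3 normal livers read 10.3 for dap on average against 1.93 in the 15 tumours, and their 3' minus 5' differences lie above those of every tumour group.

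WT tumours were first set against normal liver, to ask which genes separate the tumours from unaffected liver of the same strain. Several fetal and tumour-marker genes were far above their level in normal liver. Afp, the fetal serum protein used as a clinical HCC marker, rose by 8.97 ± 0.93 on the log2 scale (SE; 13.66 ± 0.50 in tumours, SD, n = 7, against 4.69 ± 0.60, n = 3; limma adjusted p = 7.57e-06). Gpc3, a cell-surface proteoglycan expressed in fetal liver and HCC, rose at least 50.3-fold (limma adjusted p = 8.01e-05), and Tspan8, a tetraspanin, at least 387-fold (limma adjusted p = 6.21e-07). Markers of mature male liver fell: Elovl3, a fatty acid elongase, by 6.07 ± 1.54 and Mup10, a major urinary protein, by 6.16 ± 1.80 on the log2 scale (SE; limma adjusted p = 0.00635 and 0.0138). The proliferation marker Mki67 rose at least 10.0-fold (limma adjusted p = 0.000195). For each of these genes all 7 tumours lay beyond all 3 normal livers.

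Of 9053 genes tested, 3533 changed at a limma adjusted p under 0.05, with 1701 higher and 1832 lower in WT tumours. At least 2-fold were 879 of the rises and 681 of the falls. The groups did not overlap for 3474 genes (38.4%), where chance would give 1.67%. The largest rises were those of Tspan8, Afp, Ly6d (at least 233-fold), Scd2, a stearoyl-CoA desaturase (at least 263-fold, limma adjusted p = 1.32e-09), and Akr1c18, a hydroxysteroid dehydrogenase (at least 190-fold). Scd2, Akr1c18 and Mup10 belong to families of near-identical genes whose probes may share signal, as do the Ugt2b and hepcidin genes named further on. The largest falls were those of Mup10, Elovl3, Etnppl, an ethanolamine phosphate lyase (-5.95 ± 1.40 log2, SE), Hamp2, a hepcidin gene (-5.91 ± 1.32 log2), and Obp2a, a lipocalin (at least 19.6-fold lower, limma adjusted p = 4.33e-09). Cd14, the co-receptor that passes lipopolysaccharide to Tlr4, rose at least 36.4-fold (limma adjusted p = 8.02e-06), from 2.53 ± 0.19 in normal liver to 9.18 ± 1.04 in tumours (log2, SD). The lipopolysaccharide-binding protein Lbp had a log2 change of 0.64 ± 0.70 (SE) that did not pass (limma adjusted p = 0.487). Tlr4 itself, the EGF receptor ligand Ereg and the collagen gene Col1a1 lay below the detection filter and were not tested. Their log2 group means in normal liver and WT tumours were 2.51 and 3.06 for Tlr4, 2.36 and 2.53 for Ereg, and 2.25 and 2.91 for Col1a1.

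**Figure D2:**
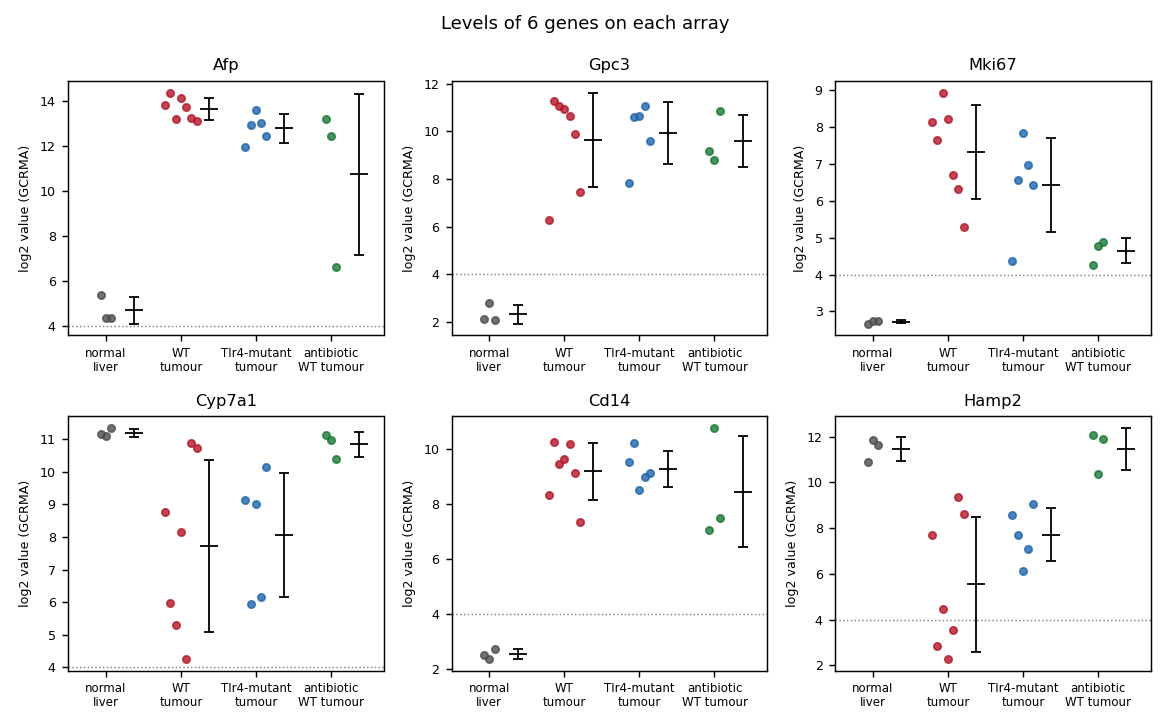
Log2 signal of Afp, Gpc3, Mki67, Cyp7a1, Cd14 and Hamp2 per array in normal liver, WT tumours, Tlr4-mutant tumours and antibiotic WT tumours, with a point per array, a bar for the mean ± SD and a dotted line at log2 4, the level of the detection filter. Afp averages 4.69 in normal liver and 13.66 in WT tumours, and Hamp2 averages 5.55 in WT tumours against 11.44 in antibiotic WT tumours.

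The gene lists were examined for functions that moved with the tumours. No list kept its camera call with an estimated correlation. Of the 20 measured oncofetal and tumour-marker genes 17 rose and none fell, with Scd2 and Igdcc4 (at least 52.9-fold) at the smallest p. Adjusted over the list alone, 18 rose. This list passed the camera test (adjusted p = 1.29e-13; adjusted p = 0.0558 with an estimated correlation). Among 21 cell cycle genes 15 rose, among them Mki67 and the ribonucleotide reductase subunit Rrm2 (2.89 log2), and the cyclin gene Ccne2 fell by 0.80 on the log2 scale (camera adjusted p = 3.83e-06; adjusted p = 0.454 with an estimated correlation). Ccne2 lay near the log2 4 limit in both groups, with means of 4.43 in normal liver and 3.63 in WT tumours. Among 14 ERK target genes 9 rose, including the phosphatase gene Dusp5 (3.75 log2) and cyclin D1, Ccnd1 (2.74 log2), while Myc fell by 2.06 on the log2 scale (camera adjusted p = 0.0025; adjusted p = 0.454 with an estimated correlation). Immediate early and heat shock genes, which also respond to handling, rose in 11 of 19 cases and fell in 1. Egr1, a growth-factor-induced transcription factor, changed by 4.04 log2 and Btg2, an antiproliferative p53 target, by 4.18 log2, while the phosphatase gene Dusp1 fell by 2.13 on the log2 scale (camera adjusted p = 0.000494; adjusted p = 0.454 with an estimated correlation). Apoptosis regulators and p53 targets rose in 9 of 22 cases, including the cell cycle inhibitor Cdkn1a (at least 18.5-fold), and caspase 9, Casp9, fell by 0.59 on the log2 scale (camera adjusted p = 0.0173; adjusted p = 0.389 with an estimated correlation). The stress response list held 7 rises among 21 genes, led by Trib3 (2.63 log2) and the transcription factor Atf4 (0.95 log2; camera adjusted p = 0.0241; adjusted p = 0.507 with an estimated correlation).

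Falls outnumbered rises in the P450, male-biased, bile acid and hepatocyte function lists. Cytochrome P450 and drug metabolism genes fell in 13 of 20 cases and none rose. Adjusted over the list alone, 14 fell and 1 rose. The glucuronosyltransferase Ugt2b5 fell by 0.81 and the carboxylesterase Ces2a by 3.07 on the log2 scale (camera adjusted p = 0.000703; adjusted p = 0.456 with an estimated correlation). All 15 male-biased liver genes had negative changes and 12 fell, including Cyp2u1 (-1.85 log2) and Susd4 (-3.89 log2; camera adjusted p = 0.00046; adjusted p = 0.454 with an estimated correlation). Female-biased genes rose in 5 of 12 cases, with the peroxisomal transporter Abcd2 at least 45.0-fold and Rtn4 1.13 log2 higher, while the monooxygenase Fmo1 fell by 1.16 on the log2 scale (camera adjusted p = 0.0105; adjusted p = 0.292 with an estimated correlation). Bile acid synthesis and transport genes fell in 14 of 25 cases and rose in 2. Slc27a5, a bile acid ligase, fell by 1.22, and Klb, the co-receptor through which Fgf19-type hormones restrain bile acid synthesis, by 2.03 on the log2 scale. The exporter Abcc4 rose at least 8.36-fold and the hydroxylase Cyp39a1 by 2.84 log2 (camera adjusted p = 0.0104; adjusted p = 0.454 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 3.47 ± 1.28 on the log2 scale (SE; 7.73 ± 2.63 in tumours, 11.19 ± 0.13 in normal liver, SD; limma adjusted p = 0.0423). Of 27 hepatocyte function genes 10 fell, among them the transcription factor Cebpa (-1.19 log2) and the urea cycle enzyme Asl (-1.47 log2), and the plasma protein gene Ahsg rose by 0.58 log2 (camera adjusted p = 0.0104; adjusted p = 0.568 with an estimated correlation).

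Rises outnumbered falls in lists of interferon-stimulated, NF-kappaB target, cholangiocyte and dendritic cell genes. Interferon-stimulated genes rose in 11 of 28 cases and none fell, with Oas1a, an antiviral oligoadenylate synthetase, 3.37 log2 and Irf9 1.58 log2 higher (camera adjusted p = 0.00046; adjusted p = 0.454 with an estimated correlation). Among 14 measured NF-kappaB targets 9 rose, including the adhesion molecule Icam1 (2.09 log2) and Tnfaip2 (1.71 log2; camera adjusted p = 0.0104; adjusted p = 0.454 with an estimated correlation). Cholangiocyte and progenitor markers rose in 4 of 8 cases, with Prom1 at least 50.3-fold higher beside Tspan8 (camera adjusted p = 0.00645; adjusted p = 0.331 with an estimated correlation). The class II antigen presentation genes H2-Eb1 (3.16 log2) and H2-Aa (1.94 log2) led 3 rises among 6 dendritic cell markers (camera adjusted p = 0.0401; adjusted p = 0.507 with an estimated correlation). Adjusted over each list alone, the rises numbered 15 for the cell cycle, 11 for immediate early genes, 11 for interferon-stimulated genes, 10 for NF-kappaB targets, 10 for apoptosis, 9 for ERK targets, 7 for the stress response, 6 for female-biased genes and 5 each for cholangiocyte and dendritic cell markers. The falls adjusted that way numbered 14 for bile acid genes, 13 for male-biased genes and 10 for hepatocyte functions.

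The other lists did not pass the camera test. Rises and falls over all genes numbered 5 and 2 of 28 acute phase genes, 6 and 0 of 16 macrophage and Kupffer cell markers, 5 and 0 of 19 stellate cell and fibroblast markers, and 1 and 1 of 20 endothelial markers. They numbered 5 and 2 of 17 TLR signalling components, 4 and 2 of 10 EGFR ligands and growth factors, 3 and 1 of 17 hypoxia genes, and 4 and 2 of 21 NRF2 targets. Among metabolic lists they numbered 3 and 0 of 18 cholesterol synthesis genes, 2 and 5 of 18 fatty acid synthesis genes, 4 and 3 of 19 PPARalpha targets, 1 and 4 of 12 periportal genes, and 1 and 0 of 15 Wnt and pericentral genes. Clock genes had 0 rises and 3 falls among 18, and erythroid markers 0 and 3 among 5. Lists with fewer than 5 measured genes were only counted: 3 rises and 1 fall among 4 adipocyte markers, 1 and 1 among 4 B cell markers, 2 and 0 among 3 neutrophil markers, 1 and 0 among 2 T and NK cell markers, and none among 2 pancreatic acinar or 3 Y-linked genes. The endothelial and PPARalpha lists had negative medians (-0.05 and -0.06 log2) beside positive means (0.09 and 0.69) and an upward test direction, and the EGFR ligand median was -0.03 with dim genes at their bound beside a mean of 0.73.

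**Figure D3:**
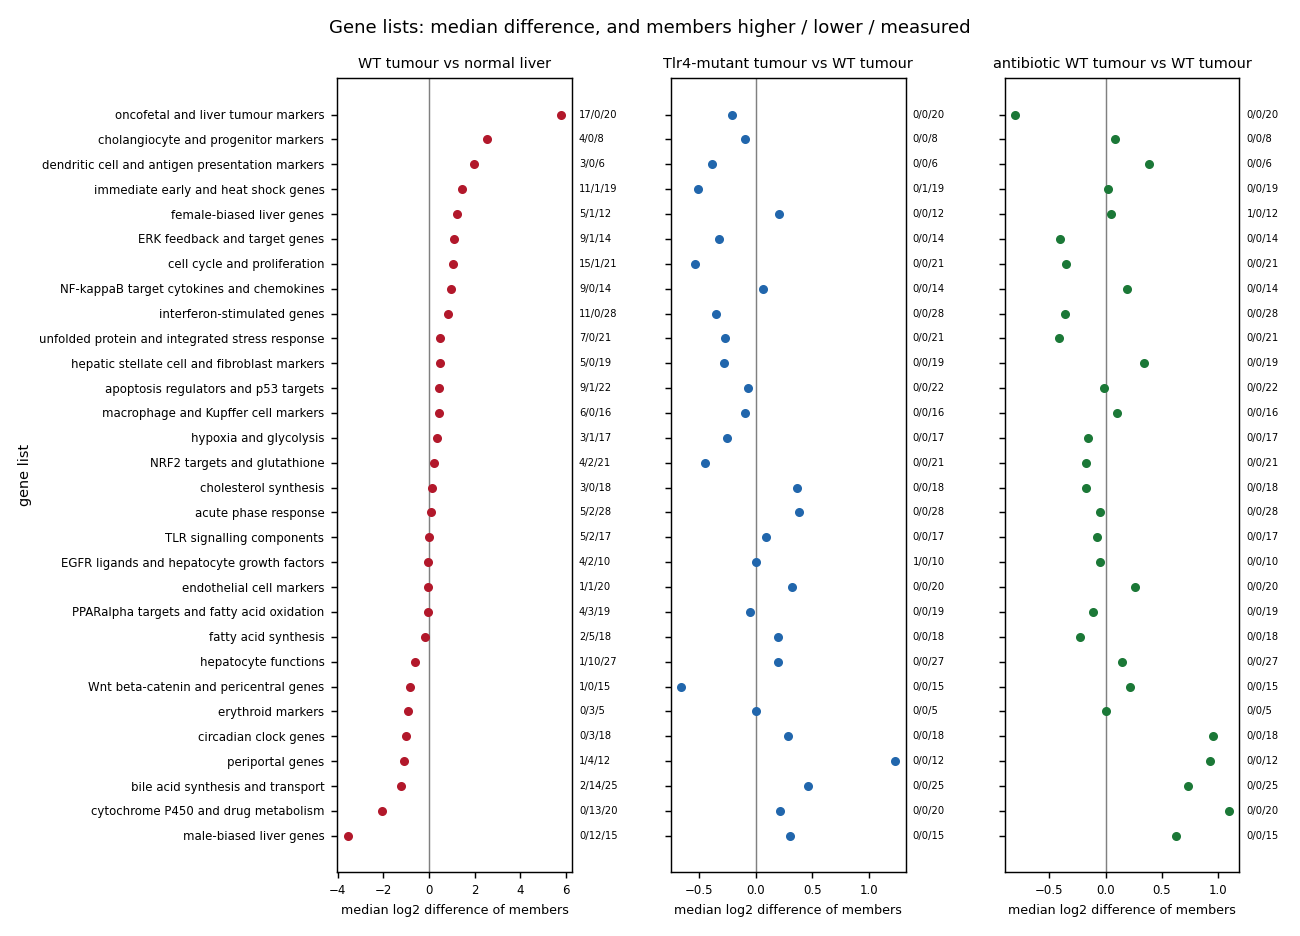
Median log2 difference of the measured members of 30 gene lists, with dim genes at their bound, for WT tumours against normal liver, Tlr4-mutant against WT tumours and antibiotic against WT tumours, each panel with its own horizontal scale. Each point is a list, and numbers beside it give the members that were higher, lower and measured; in WT tumours against normal liver the oncofetal list stands at 5.80 with 17 of 20 genes higher, and the male-biased list at -3.56 with 12 of 15 lower.

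Of the 30 lists tested 15 passed camera with its preset correlation, none with an estimated correlation (3 at an unadjusted p under 0.05) and 17 with fry. Leaving out 1 array could end a call, here with the highest adjusted p. It did so for Cyp7a1 (any normal liver, or WT tumour 17, 18, 19 or 20; adjusted p up to 0.111), Myc (any normal liver, or WT tumour 18, 19, 20, 21 or 22; up to 0.177), Ccne2 (any normal liver, or WT tumour 19; up to 0.127), Fmo1 (any normal liver; up to 0.0626), and Casp9 and Dusp1 (normal liver 2 or 3; up to 0.0962 and 0.0872). Lists lost in this way were the dendritic cell (normal liver 1 or 2, or WT tumour 16, 18, 20 or 22; up to 0.0596) and stress response lists (normal liver 2; 0.0503). The stress response list was also lost with WT tumours 17 and 19 both left out (0.0713), as were Cyp7a1 (0.0849), Casp9 (0.0523) and Ccne2 (0.0645). Cyp7a1 and Myc did not pass without the filter (0.0639 and 0.0618), nor Cyp7a1 with only the 2 groups fitted (0.0723). Without normal liver 2 the change of Cyp39a1 was 1.97 log2.

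Tlr4-mutant tumours were compared with WT tumours to ask what changes when the Tlr4 pathway is defective. The log2 changes of the liver cancer markers Afp (-0.88 ± 0.79, SE) and Gpc3 (0.29 ± 0.84) and of the co-receptor Cd14 (0.09 ± 0.59) did not pass (limma adjusted p = 0.585, 0.884 and 0.954). The genes that changed were few and of mixed function. Slc12a4, a potassium-chloride cotransporter, was at least 3.24-fold higher in mutant tumours (5.70 ± 0.79, SD, n = 5, against 2.31 ± 0.21, n = 7; limma adjusted p = 1.17e-06). Rbks, which encodes ribokinase, was at least 2.54-fold lower (limma adjusted p = 6.22e-07). Hbegf, a ligand of the EGF receptor, rose by 2.25 ± 0.42 (log2, SE; 7.50 ± 0.17 against 5.26 ± 0.59, SD; limma adjusted p = 0.0281).

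Among 9053 genes 24 changed, 13 higher and 11 lower, with 7 and 8 of them at least 2-fold, and 1512 genes had an unadjusted p under 0.05. Groups did not overlap for 146 genes (1.61%, against 0.253% by chance), which included 23 of the 24. The other large rises were those of Nme7, a nucleoside diphosphate kinase family member (2.75 ± 0.30 log2, SE; limma adjusted p = 8.31e-05), Cystm1 (2.27 ± 0.14; 9.5e-08) and Ppp1r21 (1.98 ± 0.17; 4.35e-06). The other large falls were those of Copz2, a coat protein of vesicle transport (-2.64 ± 0.28 log2, SE; limma adjusted p = 6.68e-05), Ccn1, a matricellular protein and immediate early gene (-2.20 ± 0.39; 0.0175), Pdgfa, a growth factor for mesenchymal cells (-1.78 ± 0.21; 0.000275), and Fancl, a ubiquitin ligase of DNA repair (-1.47 ± 0.19; 0.000624). In 18 of the 24 genes every mutant tumour lay outside the range of all 13 C3H/HeOuJ arrays, normal livers included. The Tlr4 change and other differences between the C3H/HeJ and C3H/HeOuJ substrains go together in these samples. All 3 measured Y-linked genes used to check the recorded sex were higher in mutant tumours, with Uty 0.91 ± 0.12 and Eif2s3y 0.89 ± 0.09 log2 above WT tumours (SE; limma adjusted p = 0.000749 and 5.95e-05). Mki67 (-0.90 ± 0.59 log2), Lbp (0.40 ± 0.60) and Cyp7a1 (0.35 ± 1.09) did not pass (limma adjusted p = 0.451, 0.758 and 0.896). Without mutant tumour 23 the change of Mki67 was -0.38.

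**Figure D4:**
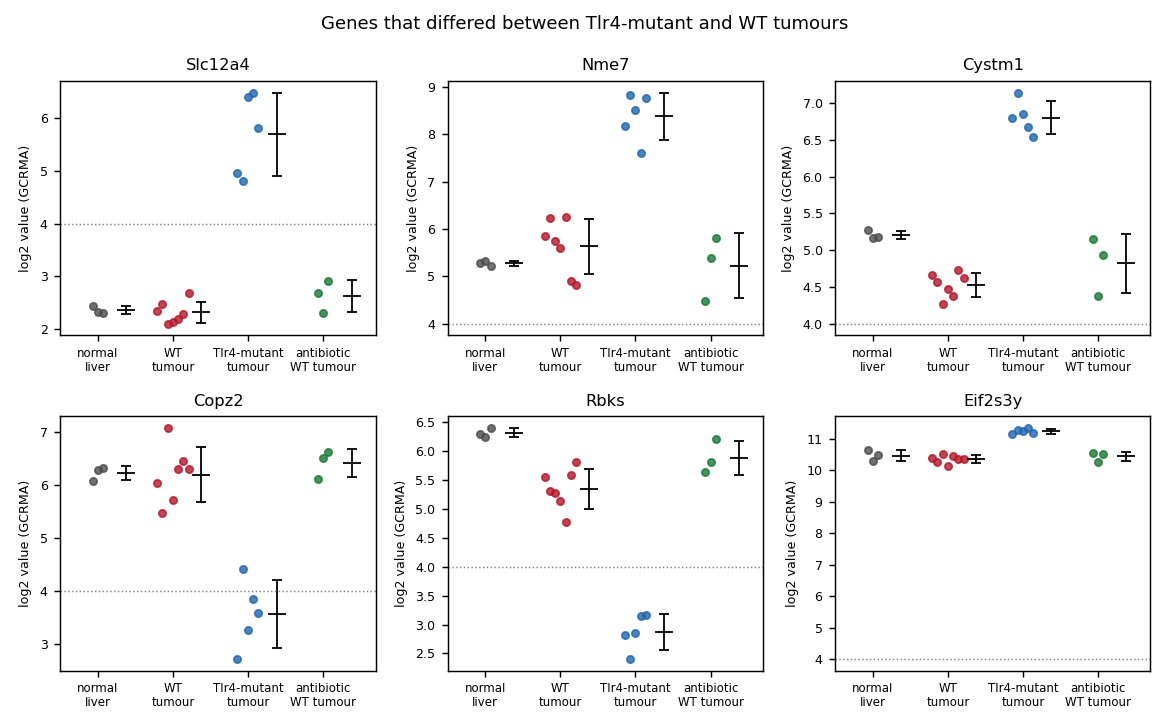
Log2 signal of Slc12a4, Nme7, Cystm1, Copz2, Rbks and Eif2s3y per array in the 4 groups, with a point per array and a bar for the mean ± SD. The 5 Tlr4-mutant tumours lie apart from the 7 WT tumours in each panel, at 5.70 against 2.31 on average for Slc12a4 and 2.88 against 5.34 for Rbks.

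Few list members passed in mutant tumours: Hbegf was the only 1 of 10 EGFR ligands and growth factors, and Ccn1 the only 1 of 19 immediate early genes. The lists that passed camera otherwise held no gene past the threshold over all genes or adjusted over the list alone, and each lost its call with an estimated correlation. All 18 cholesterol synthesis genes had positive changes, with a median of 0.37 log2 and the largest at Mvk (0.82) and Mvd (0.79; camera adjusted p = 0.000459; adjusted p = 0.740 with an estimated correlation). NRF2 targets were positive in 2 of 21 cases, with a median of -0.44 with Abcc4 at -2.76 and Slc7a11, below log2 4 in every mutant tumour, at a bound of -0.18 (camera adjusted p = 0.000459; adjusted p = 0.740 with an estimated correlation). Periportal genes were positive in 11 of 12 cases (median 1.23 log2), with Cyp2f2, a P450 enzyme, at 2.60 and Hal, a histidine-degrading enzyme, at 2.03 (camera adjusted p = 0.00572; adjusted p = 0.740 with an estimated correlation). The list means of WT tumours 17 and 19 were 8.26 and 7.37, beside 9.91 to 11.2 in the other WT tumours. With both left out Cyp2f2 was at 0.63 and Hal at 0.40. Hepatocyte function genes were positive in 23 of 27 cases (camera adjusted p = 0.000969) and acute phase genes in 24 of 28 (camera adjusted p = 0.0046; adjusted p = 0.740 with an estimated correlation for both). Interferon-stimulated genes were positive in 4 of 28 cases (camera adjusted p = 0.00345), immediate early genes in 3 of 19 (0.00345), hypoxia genes in 3 of 17 (0.00427), with Egln3 at -2.28 log2 and Ankrd37, below log2 4 in every mutant tumour, at a bound of -0.44, and stress response genes in 3 of 21 (0.00427; adjusted p = 0.740 with an estimated correlation for these lists). Cell cycle genes were positive in 5 of 21 cases (camera adjusted p = 0.00572; adjusted p = 0.754 with an estimated correlation) and Wnt and pericentral genes in 1 of 15 (0.0183; 0.775 with an estimated correlation). TLR signalling components were positive in 12 of 17 cases and NF-kappaB targets in 8 of 14, with no member past the threshold. Adjusted over the list alone, 2 of 4 B cell markers (Igha 2.35, Jchain 1.98 log2) and 2 of 3 neutrophil markers (S100a8 1.90, S100a9 1.89 log2) were higher. Lower in that way were 1 gene of the P450 and drug metabolism list (Ephx1), 1 erythroid (Hbb-b2) and 1 female-biased gene (Rtn4). Without WT tumour 19 Igha was at 1.59 and Jchain at 1.38, and with WT tumours 17 and 19 both left out at 1.16 and 0.98. These genes were chosen after their values were seen. Medians and tests differed in sign for the erythroid (0.08, test down), female-biased (0.21, test down) and NF-kappaB lists (0.06, test down), and means were -0.12, 0.28 and -0.07. The Gapdh 3' minus 5' difference was 0.24 higher in mutant tumours (two-sided exact permutation p = 0.0467, adjusted p = 0.125).

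Of 30 lists 11 passed camera, none with an estimated correlation (0 at an unadjusted p under 0.05) and none with fry (3 at an unadjusted p under 0.05). The Hbegf call was lost without WT tumour 16, 19 or 21 or any 1 of the mutant tumours (adjusted p up to 0.0949), and the Ccn1 call without mutant tumour 23, 25 or 26 (up to 0.0724), without probe sets of shared sequence (0.0511) or with the mean of its probe sets (0.14). Without mutant tumour 23 the acute phase and cell cycle lists did not pass (adjusted p = 0.13 for both), nor did the cell cycle list without WT tumour 16 (0.0595) or the Wnt list without WT tumour 17 or 19 or mutant tumour 24 or 26 (up to 0.198). Quantile normalization gave 20 rises and 11 falls. Leaving out WT tumours 17 and 19, chosen after seeing the data, gave 16 genes, with Hbegf at an adjusted p of 0.091 and Ccn1 at 0.0537. The periportal, hypoxia, immediate early and stress response lists did not pass there (camera adjusted p = 0.133, 0.183, 0.0743 and 0.0642), and the Wnt list changed direction (0.747). Abcc4 was at -1.95 log2 there and Egln3 at -1.30. Array weights added Hbb-b2 (adjusted p = 0.0184).

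Tumours of antibiotic-treated WT mice were compared with those of untreated WT mice to ask what changes when the gut bacteria are depleted. Sult1e1, the sulfotransferase that inactivates estrogens and the only gene to rise, was at least 4.47-fold higher with antibiotics (6.16 ± 1.32, log2, SD, n = 3, against 2.62 ± 0.40, n = 7; limma adjusted p = 0.000545). Malat1, a nuclear long non-coding RNA, fell by 1.19 ± 0.17 on the log2 scale (SE; 12.36 ± 0.16 against 13.55 ± 0.25, SD; limma adjusted p = 0.0178). Washc4, part of an endosomal actin-nucleating complex, fell by 1.87 ± 0.31 (limma adjusted p = 0.0312) and the phosphatase gene Ppm1h by 1.70 ± 0.31 (0.0457). Kdm5b, a histone demethylase, fell by 0.99 ± 0.16 (0.0312) and Ranbp9 by 0.89 ± 0.16 (0.0457). The other two falls, named after their values were seen, were those of Pdcd6ip (-0.64) and Pgap2 (-0.83). In all of these genes the 3 antibiotic tumours lay beyond the 7 WT tumours.

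In total 8 of 9053 genes changed, 1 higher and 7 lower, and 1401 had an unadjusted p under 0.05. Groups did not overlap for 366 genes (4.04%, against 1.67% by chance). The next genes by p among the higher ones did not pass: Hamp2 differed by 5.90 ± 1.32 log2 (SE; 11.44 ± 0.93 with antibiotics, 5.55 ± 2.94 without, SD; limma adjusted p = 0.146), Cnmd by 2.96 ± 0.65 (0.146), and Tmem238 by 1.08 ± 0.21 (0.0893). Cpsf4l (0.146) lay below log2 4 in every WT tumour and in the antibiotic mean (3.76), so no difference is given. Mki67 was lower in each antibiotic tumour than in any WT tumour, with a log2 change of -2.68 ± 0.70 that did not pass (limma adjusted p = 0.152). Afp had a change of -2.91 ± 0.93 (0.19), with 1 antibiotic tumour, number 30, at 6.63, and Cyp7a1 a change of 3.12 ± 1.28 (0.269). Gpc3 (-0.06 ± 0.99), Lbp (-0.25 ± 0.70) and Cd14 (-0.74 ± 0.70) did not pass either (limma adjusted p = 0.98, 0.887 and 0.62).

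**Figure D5:**
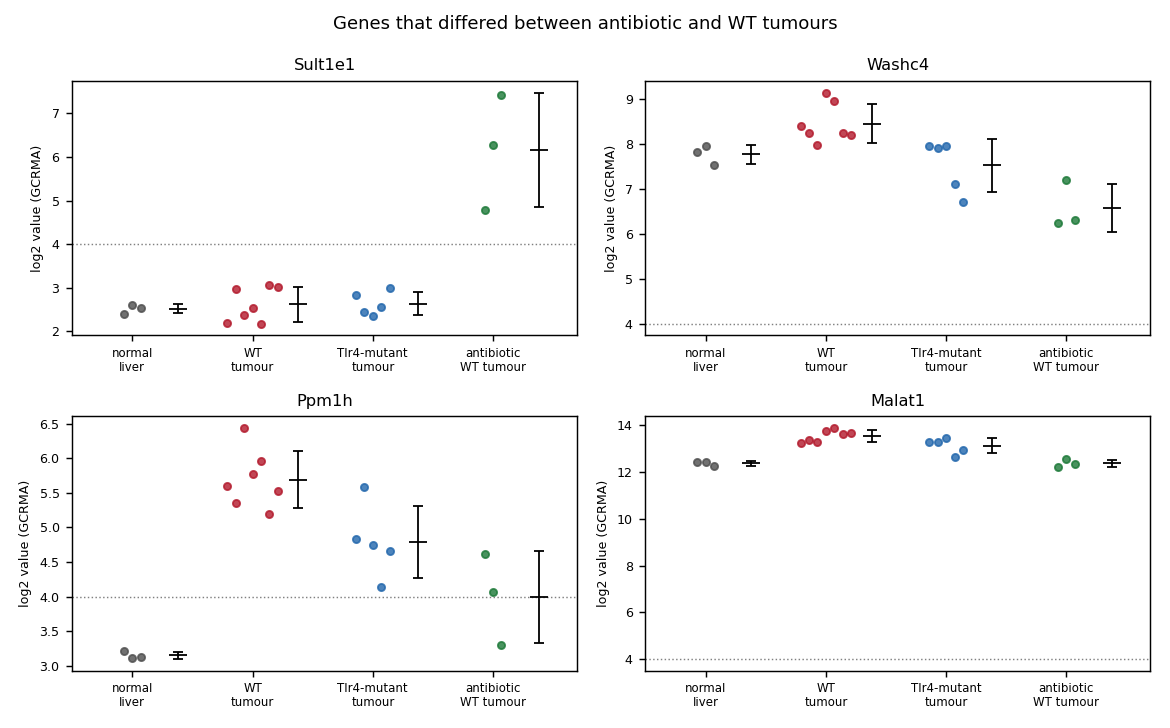
Log2 signal of Sult1e1, Washc4, Ppm1h and Malat1 per array in the 4 groups, with a point per array and a bar for the mean ± SD. The 3 antibiotic WT tumours average 6.16 for Sult1e1 against 2.62 in the 7 WT tumours, and 12.36 against 13.55 for Malat1.

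Sult1e1 was the only list member to pass over all genes, 1 of 12 female-biased genes. Among 21 cell cycle genes 7 had positive changes. The median was -1.30 log2, or -0.35 with dim genes at their bound, and the largest changes were those of Mki67 and the cyclin gene Ccnb2 (-2.39). Adjusted over the list alone 12 were lower and 1 higher, and the list passed camera (adjusted p = 0.00192; adjusted p = 0.957 with an estimated correlation). P450 and drug metabolism genes were positive in 17 of 20 cases with a median of 1.09, the largest at the acetyltransferase Nat8 (3.29) and Cyp2f2 (3.21; camera adjusted p = 0.00192; adjusted p = 0.957 with an estimated correlation). Stress response genes were positive in 3 of 21 cases, and 1 gene, Trib3, was lower when adjusted over the list alone (median -0.42; camera adjusted p = 0.00395; adjusted p = 0.957 with an estimated correlation). Oncofetal genes were positive in 4 of 20 cases, with Akr1c18 at -3.32 and Ly6d at -3.03 (median -0.80; camera adjusted p = 0.0162; adjusted p = 0.957 with an estimated correlation). These 2 values rest on antibiotic tumour 30, which read 2.90 and 3.17. Without it they were -0.65 and -0.19. Hepatocyte function genes were positive in 21 of 27 cases (median 0.15; camera adjusted p = 0.048; adjusted p = 0.957 with an estimated correlation). Adjusted over the list alone, 2 erythroid markers, Car1 (at least 1.25-fold) and Klf1 (below log2 4 in every WT tumour and in the antibiotic mean, 3.89, so no fold is given), and 1 interferon-stimulated gene, Ifit3, were higher, and 1 hypoxia gene (Ldha) and 1 immediate early gene (Zfp36) lower. These were chosen after their values were seen. The acute phase, cholangiocyte, EGFR ligand, immediate early and macrophage lists had medians (-0.05, 0.08, -0.05, 0.02 and 0.10) that differed in sign from their mean or test.

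Of 30 lists 5 passed camera, none with an estimated correlation (0 at an unadjusted p under 0.05) and none with fry (2 at an unadjusted p under 0.05). With limma fitted to these 2 groups alone no gene passed (997 at an unadjusted p under 0.05), and Sult1e1 had an adjusted p of 0.113. Leaving out single arrays kept the Sult1e1 call in all 10 fits but ended others. Without antibiotic tumour 30 only Sult1e1 passed, with Washc4 and Kdm5b at 0.164, Malat1 at 0.146 and Ppm1h and Ranbp9 at 0.25. Without antibiotic tumour 28 Washc4, Kdm5b, Ranbp9 and Malat1 were lost (up to 0.0584), and without antibiotic tumour 29 Ppm1h (0.0553). The count was 4 without WT tumour 16, 2 without WT tumour 18, 19 or 20, 28 without WT tumour 22 and 33 without antibiotic tumour 29. Ranbp9 and Ppm1h also did not pass without WT tumour 16, 17, 18, 19 or 20 (up to 0.0962 and 0.104). Nor did Washc4 without 16, 18, 19 or 20 (up to 0.0646) or without probe sets of shared sequence (-0.63 log2, adjusted p = 0.197, where Ranbp9 had 0.123), and Kdm5b without 18, 19 or 20 (up to 0.0727). Genes gained were Hamp2 without WT tumour 21 or 22 (0.0484 and 0.0453), Cnmd without WT tumour 22 (0.0435), Tmem238 without WT tumour 22 or antibiotic tumour 29 (0.0435 and 0.0437), and Cpsf4l without antibiotic tumour 29 (0.013). The hepatocyte list was lost without WT tumour 17, 19 or 20 or antibiotic tumour 28 or 30 (up to 0.372), the oncofetal list without WT tumour 17, 18 or 20 or antibiotic tumour 30 (up to 0.21), and the stress response list without antibiotic tumour 30 (0.557). With WT tumours 17 and 19 both left out the hepatocyte, oncofetal and stress response lists did not pass (camera adjusted p = 0.395, 0.0548 and 0.0548), nor did Washc4, Kdm5b, Ppm1h, Ranbp9 and Pdcd6ip (adjusted p up to 0.103). Cyp2f2 was at 1.24 log2 there and Hamp2 at 4.70. With array weights only Sult1e1 kept its call (the others up to 0.292). Ppm1h and Ranbp9 did not pass without the filter (0.081 and 0.0609), with centred arrays (0.0841 and 0.0921) or with quantile normalization (0.0821 and 0.053). Without antibiotic tumour 30 Afp was at -0.85 log2 and Nat8 at 2.43, and without antibiotic tumour 28 Cd14 was at -0.05. Pdcd6ip and Pgap2 lost their calls without 7 and 5 of the 10 arrays (adjusted p up to 0.191 and 0.173). Trib3 passed without WT tumour 22 (0.0435) and Ifit3 without antibiotic tumour 28 (0.0135).

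Tlr4-mutant and antibiotic tumours were compared directly, which tests the difference between the mutant and the antibiotic effect. Several genes that led the contrast of mutant with WT tumours changed here too, while Hbegf did not pass (2.08 log2, limma adjusted p = 0.192). Nme7 was 3.15 ± 0.37 log2 higher in mutant than in antibiotic tumours (SE; limma adjusted p = 0.000306), Slc12a4 at least 3.24-fold higher (0.000117), and Cystm1 and Ppp1r21 1.98 ± 0.17 and 1.96 ± 0.21 log2 higher (1.05e-05 and 0.000117). Rbks was at least 3.69-fold lower (limma adjusted p = 1.75e-06) and Copz2 differed by -2.86 ± 0.34 log2 (0.000384). Sult1e1, which rose with antibiotics, was at least 4.47-fold lower in mutant tumours (limma adjusted p = 0.000252). For each gene the 5 mutant tumours did not overlap the 3 antibiotic tumours.

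In all 21 genes differed, 11 higher and 10 lower in mutant tumours, with 932 at an unadjusted p under 0.05. Groups did not overlap for 5.71% of genes, against 3.57% by chance. Of the 24 genes that separated mutant from WT tumours 16 were also called here, in the same direction, but both contrasts contain the same 5 mutant tumours, so this is no independent repeat. The Y-linked genes Kdm5d (1.28 ± 0.19 log2, SE; limma adjusted p = 0.00342), Uty (1.08 ± 0.15; 0.00168) and Eif2s3y (0.81 ± 0.11; 0.00198) were higher, 3 of 3 measured. Ccn1 (-2.79 ± 0.48; 0.017), the 1 immediate early gene of 19 to change, and Plk2, a polo-like kinase (-1.64 ± 0.32; 0.0392), were lower. Afp (2.03 ± 0.99 log2), Mki67 (1.79 ± 0.74), Cd14 (0.83 ± 0.74), Lbp (0.65 ± 0.74), Gpc3 (0.35 ± 1.04) and Cyp7a1 (-2.77 ± 1.36) did not pass (limma adjusted p = 0.497, 0.416, 0.724, 0.80, 0.938 and 0.499). Without antibiotic tumour 28 the change of Lbp was 0.00289.

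Of the gene lists, all 18 cholesterol synthesis genes had positive changes (median 0.51 log2), with Mvd at 1.26 and Lss at 1.15. None passed over all genes and 1, Dhcr7, when adjusted over the list alone (camera adjusted p = 1.88e-07; adjusted p = 0.817 with an estimated correlation). TLR signalling components were positive in 15 of 17 cases, with Tlr1 at 2.33 (0.70 without antibiotic tumour 30) and Cd14 at 0.83, and no member past the threshold (camera adjusted p = 0.00888, fry adjusted p = 0.0111; adjusted p = 0.107 with an estimated correlation). Acute phase genes were positive in 25 of 28 cases (camera adjusted p = 0.00375) and P450 genes in 3 of 20 (0.00661; adjusted p = 0.879 with an estimated correlation for both). Hypoxia genes were positive in 2 of 17 cases (camera adjusted p = 0.0221), NRF2 targets in 4 of 21 (0.0221), stellate cell markers in 3 of 19 (0.0416), Wnt and pericentral genes in 1 of 15 (0.0416) and immediate early genes in 7 of 19 (0.047; adjusted p = 0.879 with an estimated correlation for these lists). Adjusted over the list alone 2 of 4 B cell markers, Igha (4.39) and Jchain (2.90), and 2 of 3 neutrophil markers, S100a8 (2.39) and S100a9 (2.18), were higher, as were 1 adipocyte marker (Cidea) and 1 EGFR ligand (Hbegf), and 2 interferon-stimulated genes (Ifit1 and Ifit3) were lower. These were chosen after their values were seen. Sult1e1 was the 1 female-biased gene of 12 to change. The apoptosis, endothelial, hepatocyte, interferon and PPARalpha medians (0.03, 0.02, 0.06, 0.01 and 0.04) differed in sign from their mean or test.

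Of 30 lists 9 passed camera, none with an estimated correlation (1 at an unadjusted p under 0.05) and 1 with fry. Fitted alone, these groups gave 3 genes, with Rbks and Cystm1 among them. The calls of Nme7 (0.0513), Copz2 (0.0586), Uty (0.0586), Ppp1r21 (0.062), Slc12a4 (0.0829), Sult1e1 (0.0886), Kdm5d (0.107), Eif2s3y (0.123), Ccn1 (0.146) and Plk2 (0.413) were lost in that fit. Plk2 was also lost without the filter (0.0695) or with array weights (0.0755), and Ccn1 with the mean of its probe sets (0.191). Without antibiotic tumour 28 S100a8 was at 1.65 log2, Hbegf at 1.26 and Cd14 at 0.14, and without antibiotic tumour 30 Afp was at -0.03. Plk2 was at -1.09 without antibiotic tumour 29. The count was 13 without mutant tumour 25 and 77 without antibiotic tumour 28. List calls numbered 5 without mutant tumour 26 and 4 without antibiotic tumour 29, where the stellate and hypoxia lists changed direction (adjusted p = 0.86 and 0.821). Plk2 was lost without mutant tumour 23, 25, 26 or 27 or antibiotic tumour 29 or 30 (adjusted p up to 0.112), and Ccn1 without mutant tumour 25 or 26 or antibiotic tumour 29 or 30 (up to 0.11). The acute phase list was lost without mutant tumour 23 or antibiotic tumour 28 (up to 0.0728), the P450 list without mutant tumour 26 or antibiotic tumour 28 (up to 0.107) and the NRF2 list without mutant tumour 26 or antibiotic tumour 28 or 29 (up to 0.249). The stellate list was also lost without mutant tumour 23, 25, 26 or 27 (up to 0.14), the Wnt list without mutant tumour 24, 25 or 26 or antibiotic tumour 28 or 29 (up to 0.259), and the immediate early list without mutant tumour 23, 24 or 26 or antibiotic tumour 28 or 29 (up to 0.86). Dhcr7 and Ifit3 passed without antibiotic tumour 28 (0.0214 and 0.00502) and Hbegf without antibiotic tumour 29 (0.00669).

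The other 2 tumour groups were set against the same normal livers, with no normal liver of C3H/HeJ or antibiotic-treated mice analysed here. Oncofetal genes rose in 15 of 20 cases in mutant tumours (camera adjusted p = 2.13e-14; adjusted p = 0.045 with an estimated correlation) and in 14 of 20 in antibiotic tumours (camera adjusted p = 1.1e-14; adjusted p = 0.0378 with an estimated correlation). Cell cycle genes rose in 9 and 5 of 21 cases, with 1 fall in mutant tumours. Male-biased genes fell in 7 and 3 of 15 cases, and P450 genes fell in 4 and 2 of 20, with 1 rise in each group. Female-biased genes rose in 3 of 12 cases in mutant and 5 of 12 in antibiotic tumours. In the antibiotic tumours that list kept its call with an estimated correlation (adjusted p = 0.0378). In mutant tumours 2015 genes changed (1061 higher, 954 lower; 39.0% of genes without overlap, against 3.57% by chance) and in antibiotic tumours 1360 (734 higher, 626 lower; 42.3% against 10% by chance). Of the lists, 17 passed camera in mutant tumours, 1 with an estimated correlation and 16 with fry. In antibiotic tumours 12, 2 and 7 did. The normal livers were too few to spare 1. Without normal liver 1, 2 or 3 the counts were 1051, 1104 and 1169 genes in mutant tumours and 604, 668 and 718 in antibiotic tumours, and 644 without antibiotic tumour 29.

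The changes of the 3 tumour groups against normal liver overlapped. WT and mutant tumours had 923 rises and 833 falls in common, where independent lists would share 199.4 and 193.1. WT and antibiotic tumours shared 637 and 539 (137.9 and 126.7 for independent lists), and mutant and antibiotic tumours 523 and 449 (86.0 and 66.0). Simulated unchanged groups, normal livers included, shared at most 1 gene over both directions. With no change simulated hardly any gene is called, so this cannot show how much of the overlap the shared normal livers create. Part of the excess may come from the shared normal livers, which were too few to be split.

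The mutant and the antibiotic effect, both taken against the 7 WT tumours, had no called gene in common in either direction, where independent lists would share 0.00144 and 0.00851. Across the 9053 genes, which are not independent replicates, the log2 changes of these contrasts had a Pearson correlation of 0.502. Simulated unchanged groups against the same WT tumours gave 0.353 on average (0.298 to 0.416 in 100 simulations). Each gene was drawn independently there, so this range leaves out the variation that genes moving together add. It therefore cannot show whether the observed correlation or covariance exceeds what shared controls give. The covariance was 0.113 beside a simulated 0.0407, a difference of 0.0719. With the WT tumours split so that each effect had its own controls, the correlation averaged 0.239 (-0.123 to 0.411 over 70 splits) and the covariance 0.0623.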

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

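The tests of other probe sets, of tissue like the normal livers, of ranges over all C3H/HeOuJ arrays and of Wnt activity were chosen after the results were seen. The limits for single genes in the test of other probe sets were set after their shares were seen.

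Among 210 groups of values (72 genes, 30 lists and 3 array measures), 7 had 1 sample far from the others by Dixon's criterion, where chance marks about 1 group in 20. In WT tumour 16 these were Egr1 at 11.2 (log2; nearest other WT tumour 12.2), Prom1 at 6.12 (9.44) and Scd2 at 10.2 (12). WT tumour 18 stood out in Fancl at 9.2 (8.52) and mutant tumour 24 in Rtn4 at 12.2 (11.8). WT tumour 17 had the lowest mean of the endothelial list, 3.55 (5.15), and of the stellate cell list, 5.69 (6.92).

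Signal outside the compared genes drew attention as well. The spiked-in control transcripts were bright on the normal arrays, with dap at 10.3, lys at 6.627, phe at 5.371 and thr at 6.982 (log2 means), and at 1.93, 2.15, 2.21 and 1.91 on the tumour arrays. Of 1974 kept probe sets without a single gene symbol, 756 changed in WT tumours against normal liver (404 higher, 352 lower), 9 in mutant against WT tumours (5 and 4), 3 in antibiotic against WT tumours (0 and 3), 11 in mutant against antibiotic tumours (11 and 0), 546 in mutant tumours against normal liver (272 and 274) and 428 in antibiotic tumours against normal liver (206 and 222), each at a limma adjusted p under 0.05.

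Other splits of the same arrays show what the gene counts can bear. For WT tumours against normal liver 1 of 100 splits, the real one, gave as many as its 3533 genes, and the highest other gave 729. For mutant against WT tumours 3 of 100 splits, the real one included, gave at least 24 genes, a share under 0.05. The highest other split gave 439 genes. This points to a structure of the samples that can give more calls than the real groups, so the share alone does not exclude chance. The split with 439 genes set WT tumours 16 to 20 against WT tumours 21 and 22 and the mutant tumours. WT tumours 17 and 19 were on the same side in it and in the other split with at least 24 genes, as in 43 of all 99 other splits. For antibiotic against WT tumours chance could not be excluded: 8 of 100 splits gave at least 8 genes and the highest other 576, which again points to a structure. In 6 of the 7 other splits that large WT tumours 17 and 19 were on the same side, as in 52 of all 99 other splits. After these results were seen, the mean of the clock gene list was found to take a low or a high level in the tumours. It read 6.32 to 6.68 in WT tumours 16 to 20 and 6.17 and 5.99 in mutant tumours 23 and 24. In WT tumours 21 and 22 it read 7.37 and 7.44, in mutant tumours 25 to 27 7.40 to 7.66 and in antibiotic tumours 7.29 to 7.58. In normal liver it read 7.49 to 7.67. All contrasts but that of antibiotic tumours with normal liver are therefore unbalanced in this level, whose cause was not tested. The split with 439 genes separates the WT tumours along this level. For mutant against antibiotic tumours only the real split, 1 of 56, gave as many as its 21 genes, with 11 in the highest other. Fitted alone these 2 groups gave 3 genes. For mutant tumours against normal liver only the real split, 1 of 56, gave as many as its 2015 genes, with 856 in the highest other. A share of 1 of 56 is the smallest these splits could give. Where only the real split reached its count, chance is still not excluded, because the arrays of a group may not be independent samples. The 10 splits of antibiotic tumours and normal livers are too few for a share under 0.05; the real count was 1360, reached by 1 split, and the highest other 1.

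The counts of lists past camera did not stand out from other splits. As many lists passed in 21 of 100 splits for WT tumours against normal liver (15; highest other 19), 42 of 100 for mutant against WT tumours (11; 18), 100 of 100 for antibiotic against WT tumours (5; 17), 33 of 56 for mutant against antibiotic tumours (9; 15) and 4 of 56 for mutant tumours against normal liver (17; 20), so chance could not be excluded for any of these. For antibiotic tumours against normal liver 10 splits are too few, with 12 lists in the real split, reached by 5, and 15 in the highest other.

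The genes that separate mutant from WT tumours formed the first pattern weighed. In 18 of the 24 genes all mutant tumours lay outside all 13 C3H/HeOuJ arrays, as in 28 of all tested genes where chance would give 2.11. Substrain differences and the Tlr4 change cannot be told apart for any of the 24, because every mutant array is C3H/HeJ. Either would give such ranges, so the ranges cannot decide between them. A sequence variant under a single probe set is argued against as the sole cause in 10 of the 13 genes with another kept probe set. In these the other probe sets moved the same way by more than 2 SE, with a median share over 0.5 of the change. The share was 0.534 in Rbks and 0.583 in Hccs, so a variant that adds part of the change is not excluded. The other 3 genes did not meet these limits. The shares were 0.146 in Cltb, -0.266 in Rac1 and 0.7285, -0.109 and -0.4796 in Lcorl, where 1 of 3 other probe sets followed, so a variant and a difference between transcripts cannot be told apart there. For the 11 genes with 1 kept probe set, a variant under the probes and a change in expression cannot be told apart, since no other probe set measures them. An effect of Tlr4 itself stays open.

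The second pattern was higher P450 and lower cell cycle genes in antibiotic than in WT tumours. In 36 genes abundant in normal liver and at least 8-fold lower in mutant tumours, the median change was 1.12 log2 (95% bootstrap interval 0.793 to 2.04, 30 of 36 positive). This lay near the P450 median of 1.09, as more surrounding liver tissue in these samples would give. The interval resampled genes, not tumours, so it leaves out the spread between tumours. The 36 genes also held P450 genes outside that list, such as Cyp7b1 and Cyp4a12a, so the similar median is not separate evidence. A P450 change of this size needs a share of 25.5% tissue like the 3 normal livers. In the group means 24 of the 36 genes stayed below the level that share would give, 13 of them by more than 1 log2 unit. This argues against an equal share of that size in all 3 antibiotic tumours. Uneven shares are not excluded, since the means join unlike tumours: Hsd3b5 read 11, 9.95 and 2.35 in antibiotic tumours 28, 29 and 30. The 25.5% is also a median over the P450 list, so single genes of that list need more or less. Surrounding liver of treated, older mice was not measured here and stays open, as do more differentiated tumours and an effect of the antibiotics.

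The third pattern was WT tumours 17 and 19, apart from the other tumours on the second principal component. For normal pericentral liver in the dissected tissue, 35 genes abundant in normal liver were examined, with pericentral and periportal list members left out. Their median deficits were -5.21 and -5.89 log2 there, larger than the median of the other WT tumours (-2.99, range -1.6 to -6.05). WT tumours 18 and 20 had larger deficits still, -5.98 and -6.05. This argues against much normal liver of mixed zones. The genes were chosen on whole liver, so pericentral cells alone are not excluded. Wnt beta-catenin activity in these tumours is a hypothesis that the values may fit: the higher of their periportal list means was 8.26, below the lowest other tumour at 9.91, and their Wnt list means of at least 10.81 exceeded the highest other tumour at 9.28. These means leave out Axin2, Lgr5, Nkd1, Notum and Sp5, which the filter removed for not exceeding log2 4 on 3 arrays. Their highest values were 7.885, 9.014, 7.482, 6.983 and 5.156. The arrays that gave these values were not examined, so the filter may hide signal confined to 1 or 2 tumours. The design names no group that sets these tumours apart, so no biological explanation from the design was tested.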

How the results depend on the processing

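Leaving out WT tumours 17 and 19 together was the alternative chosen after the data were seen; the others were planned, and all were run. Comparisons are given in the order WT tumour against normal liver, mutant against WT, antibiotic against WT, mutant against antibiotic, mutant against normal and antibiotic against normal.

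All kept probe sets one by one gave 6652, 65, 92, 35, 4051 and 3063 calls, with more units tested. A 2-fold minimum gave 1560, 15, 4, 16, 925 and 663 genes, and an adjusted p under 0.01 gave 1996, 14, 1, 13, 833 and 448, as stricter thresholds must. Array weights gave 38 genes for mutant against WT, 1 for antibiotic against WT and 4684 for mutant against normal; the cause was not tested. A limma fit of only the 2 groups compared gave 0 genes for antibiotic against WT (997 at an unadjusted p under 0.05) and 3 for mutant against antibiotic (739), with fewer samples to estimate the spread. For antibiotic against WT the mean of a gene's probe sets gave 17, arrays centred on their median 5 and WT tumours 17 and 19 left out 4; the cause was not tested.

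Lists past the threshold with an estimated inter-gene correlation numbered 0, 0, 0, 0, 1 and 2. With fry they numbered 0 for mutant against WT, 0 for antibiotic against WT, 1 for mutant against antibiotic and 7 for antibiotic against normal. At an unadjusted p under 0.05 the estimated correlation gave 3, 0, 0, 1, 4 and 3 and fry 17, 3, 2, 2, 17 and 13. The correlation of the mutant and antibiotic effects was 0.239 with the WT tumours split, where the effects no longer share controls.

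Leaving out 1 array gave 2383 to 3588 genes (lowest without normal liver 2), 16 to 34 (lowest without mutant tumour 25, highest without WT tumour 22), 1 to 33 (without antibiotic tumour 30 and 29), 13 to 77 (without mutant tumour 25 and antibiotic tumour 28), 1051 to 2131 and 604 to 1460 (lowest without normal liver 1 in both). Lists numbered 13 to 17, 9 to 12, 3 to 9, 4 to 13, 16 to 19 and 8 to 15, and the correlation was 0.347 to 0.592. Fewer samples took part in these fits.

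The reversed changes of named genes had not passed, while 3 reversed lists had. In mutant against WT tumours Cyp7a1 was -0.156 with the mean of its probe sets and -0.0136 with array weights, Cd14 was -0.0498 with array weights, and the Wnt list had an adjusted p of 0.747 in the other direction with WT tumours 17 and 19 left out. Gpc3 in antibiotic against WT tumours was 0.52 with those tumours left out. Leaving out 1 array moved Gpc3 between -0.272 and 0.823, Cd14 between -0.218 and 0.278, Cyp7a1 between -0.23 and 0.878 and Lbp between -0.0263 and 0.783 in mutant against WT tumours. It moved Gpc3 between -0.677 and 0.349 and Lbp between -1.1 and 0.394 in antibiotic against WT tumours, and Gpc3 between -0.0578 and 0.969 and Afp between -0.0269 and 3.25 in mutant against antibiotic tumours. Without a reversal it moved Mki67 between -1.25 and -0.38 in mutant against WT tumours, Cd14 between -1.9 and -0.0491 in antibiotic against WT tumours, and Lbp between 0.00289 and 1.5 and Cd14 between 0.138 and 1.99 in mutant against antibiotic tumours. In that comparison the stellate list ranged from an adjusted p of 0.00174 to 0.86 and the hypoxia list from 3.24e-05 to 0.821, both reversed without antibiotic tumour 29. The cause of these reversals was not tested.

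Values of named genes under other settings kept direction and side of the threshold in 615 cases and lost the call in 18 for WT tumours against normal liver, 425 and 8 for mutant against WT (1 gained a call), 323 and 45 for antibiotic against WT (1 gained) and 341 and 16 for mutant against antibiotic. With 1 array left out the numbers were 464 and 26, 388 and 11, 235 and 39 (8 gained) and 225 and 10 (3 gained). Named lists kept their call under other settings in 44 cases and lost it in 16, 17 and 26, 7 and 13, and 10 and 17; with 1 array left out in 143 and 7, 125 and 7, 40 and 10, and 49 and 21. No paired analysis was possible because no sample numbers are shared between groups.

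Signal over background limits what can be said of dim genes: Tlr4, Ereg and Col1a1 stayed below log2 4 on every array, so a change in them was not detectable, and 371 of the genes changed between WT tumours and normal liver had a dim normal group, so that their folds are bounds.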

Other observations

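The test of Wnt activity named here was chosen after the result was seen, as were all genes of this part, whose values had been seen first.

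WT tumours 17 and 19 expressed genes of the liver zone around the central vein at levels above the other tumours. Glul, the glutamine synthetase of that zone, read 12.7 and 13.1 (log2; at most 11.6 in the other tumours), Lect2 12.9 and 13.3 (at most 10.8), Oat, an ornithine-metabolising enzyme, 13.3 and 13.8 (at most 11.9), and the transcription factor Tbx3 8.59 and 10.1. The ammonium transporter Rhbg read 7.66 and 9.13. Genes of the zone around the portal vein were low in the same tumours: Cyp2f2 read 2.92 and 3.58 and Hal 5.26 and 4.58. Hamp, the iron hormone hepcidin, read 2.84 and 6.6. Beta-catenin signalling is the known regulator of this zonation, and with a periportal mean of at most 8.26 in these tumours its activity is a candidate explanation, which no mutation data used here can test. Pnliprp1, a pancreatic lipase-related gene, read 9 and 8.44 in them and 5.88 in mutant tumour 23.

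Single tumours differed in other programmes. Adm, a hypoxia-induced hormone, read 9.26 in antibiotic tumour 29, 6.28 in WT tumour 17 and 5.06 in WT tumour 19, and Ankrd37 read 6.65, 7.67 and 5.45 in these. Ndrg1, a stress-induced gene, read 12 and 11.9 in WT tumours 17 and 19. Cd74, the invariant chain of antigen presentation, read 8.36 and 8.66 in antibiotic tumours 29 and 30 and 4.74 in antibiotic tumour 28. Antibiotic tumour 30 had little Afp (6.63) and Hsd3b5 (2.35), a male-biased steroid enzyme, and lay at -65.6 on the third principal component, which held 8.95% of the variance.

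Hamp averaged 13.07 in normal liver, 12.04 in mutant tumours and 12.55 in antibiotic tumours. In WT tumours it ranged from 2.84 to 12.1, and tumours 17 and 19 were the lowest. The Y-linked gene Eif2s3y read between 10.1 and 11.4 on every tumour array.

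When every kept probe set was tested in antibiotic against WT tumours, 92 were called, 90 of them lower. Of these 66, in 61 genes, were not the brightest probe set of their gene, and all 66 were lower. They were picked for having passed, so their changes cannot be set against those of the brightest probe sets. The cause was not tested.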
